A study of Mus musculus with 4 samples.

How the data were processed

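RNA from the telencephalon, the embryonic forebrain, was sequenced from mouse embryos at embryonic day 14. There were 4 libraries, 2 from controls carrying a loxP-flanked (floxed) Ctcf gene and 2 from Ctcf-null embryos that also carried Cre recombinase driven by Nestin sequences, which is active in neural progenitor cells. Per the labels' protocols, tissue was kept in RNAlater, and cDNA was made with a Clontech SMART cDNA kit before Illumina libraries were prepared. The labels name no molecular identifiers and no strand information, so reads from overlapping or antisense genes cannot be told apart. The intervals printed below are of odds ratios across genes, and they do not cover the spread between embryos. Nothing in the labels says that the libraries came from separate embryos, so the p-values measure only the spread between these samples, which may be technical.

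The authors deposited 1 table of 48795 genes, with versioned Ensembl gene identifiers and symbols. Per the submitters' processing notes, STAR 2.5.3, DESeq2 and the mm10 genome were used. The gene counter and the annotation release are not given in the sources used here. Per the file headers, the authors' values per library are normalized read counts, a signal without division by gene length. In each library nearly every value was a whole multiple of 1 step. Dividing by that step returned whole reads for at least 99.992% of nonzero values in each library, within a tolerance of 0.005 on the deposited value. One read was worth 0.889 in control 1, 1.25 in control 2, 0.707 in Ctcf-null 1 and 1.21 in Ctcf-null 2. The recovered reads therefore give the depth, which was 41294659 reads in control 1, 27619441 in control 2, 43812558 in Ctcf-null 1 and 25519331 in Ctcf-null 2. The authors' deposited log2 fold changes per pair were recomputed as the log2 of (Ctcf-null + 1)/(control + 1) with gaps of at most 0.008, and their average is the mean of both pairs.

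The design fixed before the data were examined was a count test with genotype as the only term, to be replaced by limma on log2(value + 1) if the table held normalized values. It did, so limma 3.58.1 (R 4.3.3) was run with a mean-variance trend on log2(normalized count + 1), with 22158 genes left by filterByExpr in edgeR 4.0.16. Fold changes from that fit are on the log2(value + 1) scale, which understates the change of genes with low counts. A replicate block was fixed at the same time as an alternative to the count test. It was run as edgeR's quasi-likelihood test on the recovered reads with TMM factors, called the paired fit below. The design did not name reads recovered from normalized values. Running the block in edgeR instead of limma was therefore decided after the table was seen. Tests of genes were two-sided, with Benjamini-Hochberg adjustment and a threshold of 0.05. The permutation tests of neighbouring genes were one-sided (as many or more) and not adjusted. Standard errors in the paired fit are approximate, the fold change divided by the square root of its F statistic. DESeq2 1.42.0 and limma-voom were run as alternatives.

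The replicate numbers were taken as pairing the samples, because the submitters' design text speaks of 2 pairs and the deposited table gives a fold change for each pair. What the members of a pair share is not given in the sources used here. Across the 22158 genes, which are not independent replicates, libraries with the same number correlated at r = 0.987 and 0.984 on the log2 scale, and libraries with different numbers at 0.887 to 0.903. The deviations of same-numbered libraries from their group means correlated at 0.923. The median absolute log2 difference was 0.84 between pairs and 0.20 between genotypes. Counts of the 2 controls differed far beyond sampling noise (chi-square per degree of freedom 499), as did those of the 2 Ctcf-null libraries (402). None was therefore counted as a repeat sequencing of another library, though separate preparations of 1 sample could also exceed that noise. Within the pairs the values were lower, at 37.7 and 15.1. Both fits are therefore reported, with most values of single genes from the fit with the block. The paired fit leaves 1 residual degree of freedom and rests on a spread shared across genes (prior degrees of freedom 23.6).

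On simulated counts with the pair difference of these libraries (21627 genes run, 200 changed), the paired edgeR fit recovered 71.6% of the genes changed 1.5-fold, 91.0% of those changed 2-fold and 98.5% of those changed 4-fold, with 10 false calls. The limma fit without the block recovered 0% at each size. DESeq2 with the block recovered 43.3%, 77.6% and 90.9%, with 0 false calls. The counts were drawn with the spread that the paired fit had estimated as a trend on expression, without added spread of single genes. The changed genes had a mean of at least 1 CPM. The rates with the block are therefore a best case.

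Before the data were examined, 30 gene lists were fixed. They were tested with camera at a preset inter-gene correlation of 0.01, and beside it with an estimated correlation and with fry. Without the block 14 lists passed, and with it 16. The camera adjusted p without the block was 1.4e-07, 6.5e-58 and 2.5e-07 for the alpha, beta and gamma protocadherins. It was 2.3e-05 for interneuron, 0.0018 for intermediate progenitor and 1.2e-04 for excitatory neuron genes. For DNA replication it was 0.0026, for mitosis 0.0037 and for the integrated stress response 0.0073. For microglia it was 0.028, for choroid plexus 0.022 and for the interferon response 0.0018. With an estimated correlation no list passed in either fit (0 of 30), nor with fry's directional test (0 of 30). Both tests rest on the residual degrees of freedom, 1 with the block and 2 without it. They had little power here, so a list that failed them is not shown to be unchanged. The lists that passed rest on the preset correlation. The estimated-correlation p is printed beside each list that passed.

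The rule for named genes, also fixed beforehand, took Ctcf first. It then took the 8 largest rises and the 8 largest falls among genes past the threshold whose Ctcf-null libraries both lay on one side of both controls, with a mean of at least 1 CPM and without predicted-only names. From each list it took the 2 called members with the smallest adjusted p, or, where none was called, the most abundant member as a value. Since under 10 genes passed without the block, the 10 genes with the smallest p are given as values. The rest of the rule was applied to the paired fit, a choice made after the result without the block was seen. Further list members named below were chosen after their values were seen.

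Coordinates are 1-based, on GRCm38 (mm10), from GENCODE M21, to which 48435 of the identifiers matched without their version. The table repeats 124 symbols, and for 25 rows the GENCODE name was used instead. One of these is the gene listed as a second Pcdhga8, which is Pcdhgc4 there. Alternatives covered scaling factors, tool, filter, pseudocount, threshold, abundant genes, left-out libraries, and trends on GC content and exon length. Those chosen after seeing the data were the edgeR fit without the block, other pseudocounts, limma with the block, and all variations of the paired fit. The use of recovered reads was also decided then.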

Results

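The study compared the embryonic day 14 telencephalon of control and Ctcf-null mice. CTCF is a zinc finger protein that binds DNA and, with the ring-shaped cohesin complex, anchors chromatin loops. The question was which transcripts differ when the gene is removed from neural progenitors and their descendants. Each genotype had 2 libraries, numbered as 2 pairs, with 25519331 to 43812558 reads per library. Reads were found for 37171 genes in control 1, 31760 in control 2, 38327 in Ctcf-null 1 and 32473 in Ctcf-null 2. The 10 most abundant genes took 26.0% of the reads in control 1 and 21.9% in Ctcf-null 1, against 8.8% and 8.4% in the second pair. All 4 libraries expressed Y-linked genes, with Ddx3y at 911.16 to 1370.63 normalized counts and the X-inactivation transcript Xist at 1.21 to 6.23.

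In Ctcf-null telencephalon the Ctcf transcript was 13.9-fold lower in the fit that compares libraries within pairs (the paired fit, 2 libraries per genotype). In the same fit all 19 measured protocadherins of the beta cluster fell, as did Sst, the interneuron peptide somatostatin (8.55-fold lower), and the proneural gene Neurod1 (3.07-fold lower). The urea transporter gene Slc14a1 was 18.6-fold higher. None of these genes passed in the limma fit without the block of pairs. Fold changes, SE and list tests below are of the paired fit unless another fit is named. Without the block the limma SE was 1.07 for Sst, 0.32 for Neurod1 and 0.42 for Slc14a1. In the paired fit it was 0.09, 0.08 and 0.12.

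Ctcf itself (ENSMUSG00000005698.15, chromosome 8, 105636568 to 105682922, plus strand) was lower in both Ctcf-null libraries. Its normalized read count was 436.72 and 1133.21 in controls 1 and 2, and 38.89 and 61.96 in Ctcf-null 1 and 2. The log2 fold change was -3.81 without the block (SE 0.65, limma adjusted p = 1.00) and -3.80 in the paired fit (SE 0.15, edgeR adjusted p = 2.6e-15). The fold changes of the single pairs were -3.41 and -4.13. The authors' deposited table gives -3.46 and -4.17 for the pairs.

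Without the block, no gene passed the threshold in limma (0 of 22158), while 170 had an unadjusted p under 0.05. The counts were 0 and 174 in edgeR and 0 and 163 in limma-voom, whereas DESeq2 without the block called 9 genes, 7 higher (Slc14a1, D830044I16Rik, Gm37933, C130021I20Rik, Cmpk2, Gm26706 and Gm38250) and 2 lower (Nxph2 and Ctcf), with adjusted p of 4.1e-05 to 0.026. The 10 genes with the smallest p in limma did not pass (adjusted p = 1.00) and are given as values. They were Slc14a1, Nxph2, Cmpk2, Pcdhb9 and Pcdhb19, which are described below, and 5 transcripts with predicted or clone names. D830044I16Rik was at 12.45 and 16.26 normalized counts in controls and 243.24 and 374.18 in Ctcf-null libraries. Gm37933 was at 5.34 and 3.75 against 98.29 and 176.16, and the antisense transcript Gm38250 at 72.04 and 81.3 against 562.15 and 577.07. The antisense C130021I20Rik had 1 read in each control, against normalized counts of 54.45 and 167.65. The non-coding 1700011D18Rik had 0 reads in control 1 and 1 in control 2, against normalized counts of 41.01 and 78.97. In the paired edgeR fit these 5 transcripts passed, with adjusted p of 2.9e-14 (Gm38250) to 1.1e-08 (1700011D18Rik).

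In the paired fit, 2643 genes passed (11.9% of those tested), of which 1063 rose and 1580 fell in Ctcf-null telencephalon. From here on, rose and fell refer to genes past the adjusted p of 0.05 in that fit. Of the called genes, 98.6% had the same sign in both pairs, against 61.5% of genes not called. The fit favours genes whose 2 pairs agree, so this difference follows in part from the selection and is no separate evidence. Most changes were small, with a median absolute log2 fold change of 0.53. A change of 2-fold or more was found for 267 genes that rose and 248 that fell, and of 4-fold or more for 48 and 51. Across genes, the fold changes of the 2 pairs correlated at r = 0.41 and rho = 0.39. The balance of rises and falls depended on scaling. Rises were 40.2% of the calls with TMM factors, 26.1% (848 against 2399) with the authors' size factors, 26.7% (813 against 2228) in limma with the block, and 56.0% (1358 against 1069) with upper-quartile factors. DESeq2 with the block called 832 genes, all of them also called by edgeR in the same direction. Across tested genes, which are not independent replicates, the paired fold change correlated with the authors' deposited average at r = 0.954. Of 794 tested genes whose deposited average was 1 or more in size, 496 were called.

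**Figure D1:**
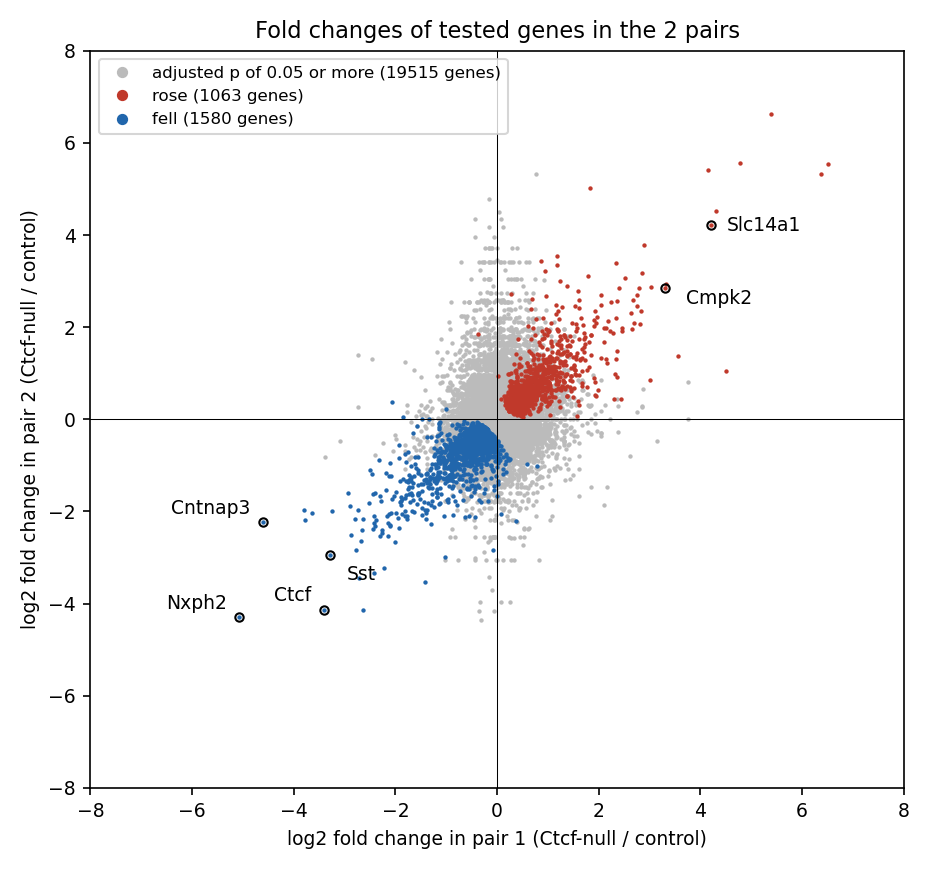
Each point is 1 of 22158 tested genes, with its log2 fold change (Ctcf-null over control) in pair 1 on the horizontal axis and in pair 2 on the vertical axis. The 1063 genes that rose (red) and the 1580 that fell (blue) in the paired fit lie mostly toward the upper right and lower left, with Ctcf at -3.41 and -4.13.

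The largest rise by the naming rule was that of Slc14a1, a urea transporter gene (chromosome 18, 78100091 to 78142119), from 93.39 and 67.54 normalized counts in controls to 1653.22 and 1225.82 in Ctcf-null libraries (log2 fold change 4.21, SE 0.12, edgeR adjusted p = 2.8e-18). Cmpk2, a mitochondrial nucleotide kinase gene (chromosome 12, 26469204 to 26479837), rose by 3.10 (SE 0.11). Mnd1, which acts in meiotic recombination (chromosome 3, 84087933 to 84155786), rose by 3.10 (SE 0.13) and Pkib, an inhibitor of protein kinase A (chromosome 10, 57631981 to 57741112), by 3.05 (SE 0.15). The ADP-ribosyltransferase gene Parp3 rose by 2.75 (SE 0.27), the calcium pump regulator Sln by 2.65 (SE 0.15), the neuromedin B receptor gene Nmbr from 17.79 and 26.27 to 108.19 and 127.56 normalized counts (SE 0.24) and the phosphatase regulator Ppp1r17 by 2.39 (SE 0.20). Adjusted p for these 7 genes lay between 2.0e-16 and 3.8e-08.

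The largest fall was that of Nxph2, which encodes a neurexophilin, a secreted ligand of neurexins (chromosome 2, 23321246 to 23401973), from 164.55 and 207.63 normalized counts to 4.24 and 9.72 (log2 fold change -4.76, SE 0.28, edgeR adjusted p = 2.4e-12). Cntnap3 (chromosome 13, 64736182 to 64903955) followed with -4.03 (SE 0.39), though its pairs differed, at -4.60 and -2.23. Sst, the somatostatin gene (chromosome 16, 23889573 to 23890958), went from 1491.59 and 5444.67 to 146.37 and 679.12 (log2 fold change -3.10, SE 0.09, adjusted p = 6.1e-18). Def8 (chromosome 8, 123423527 to 123463270) had -2.80 (SE 0.11) and Fam196b -2.62 (SE 0.31). The protocadherins Pcdhb9, at -2.98 (SE 0.23), and Pcdhb19, at -2.75 (SE 0.24), completed the group. Adjusted p for these 5 genes lay between 1.2e-15 and 8.4e-07.

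**Figure D2:**
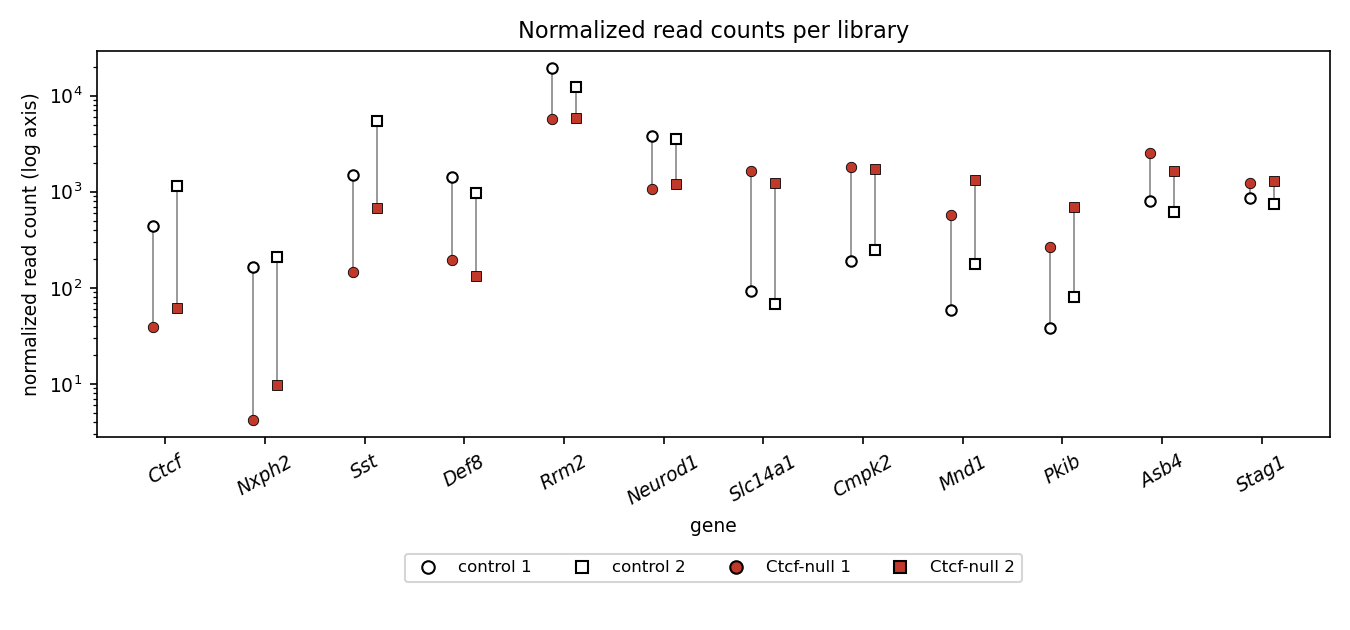
Normalized read counts (log axis) of 12 named genes in each of the 4 libraries, with controls as open symbols and Ctcf-null libraries as red symbols, circles for pair 1 and squares for pair 2, and a line joining the members of a pair. Ctcf stands at 436.72 and 1133.21 in controls and at 38.89 and 61.96 in Ctcf-null libraries.

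The clustered protocadherins, adhesion molecules encoded in tandem on chromosome 18, formed the group with the largest shift. In the beta cluster 19 of 19 measured genes fell (19 also when adjusted over the list alone), with a median log2 fold change of -2.08. Pcdhb9 fell, as given above, and Pcdhb7 (37341702 to 37345202) went from 385.13 and 285.18 normalized counts to 103.94 and 69.25 (log2 fold change -1.89, SE 0.14). The camera adjusted p was 6.4e-38 in the paired fit (adjusted p = 0.60 with an estimated correlation). Without the block, 15 of the 19 passed when adjusted over the list alone. In the alpha cluster 8 of 11 measured genes fell and 1 rose (8 and 1 adjusted over the list alone), with a median of -1.33 and a camera adjusted p of 5.1e-06 (adjusted p = 0.60 with an estimated correlation). Pcdha7 fell by 2.41 on the log2 scale (SE 0.38), whereas Pcdhac2, the last variable exon gene before the constant exons, rose by 1.42 (SE 0.18), from 57.81 and 72.55 to 130.11 and 215.03 normalized counts. In the gamma cluster 11 of 20 fell and 3 rose (13 and 3 adjusted over the list alone), with a median of -1.01 and a camera adjusted p of 1.3e-06 (adjusted p = 0.63 with an estimated correlation). Pcdhga11 fell by 1.67 (SE 0.15), while Pcdhgc4 rose by 1.08 (SE 0.10). The other gamma genes that rose were Pcdhgc3 at 0.77 and Pcdhgb4 at 0.89. The values of single alpha and gamma genes are uncertain, because these genes share their constant exons and the annotated genes overlap.

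**Figure D3:**
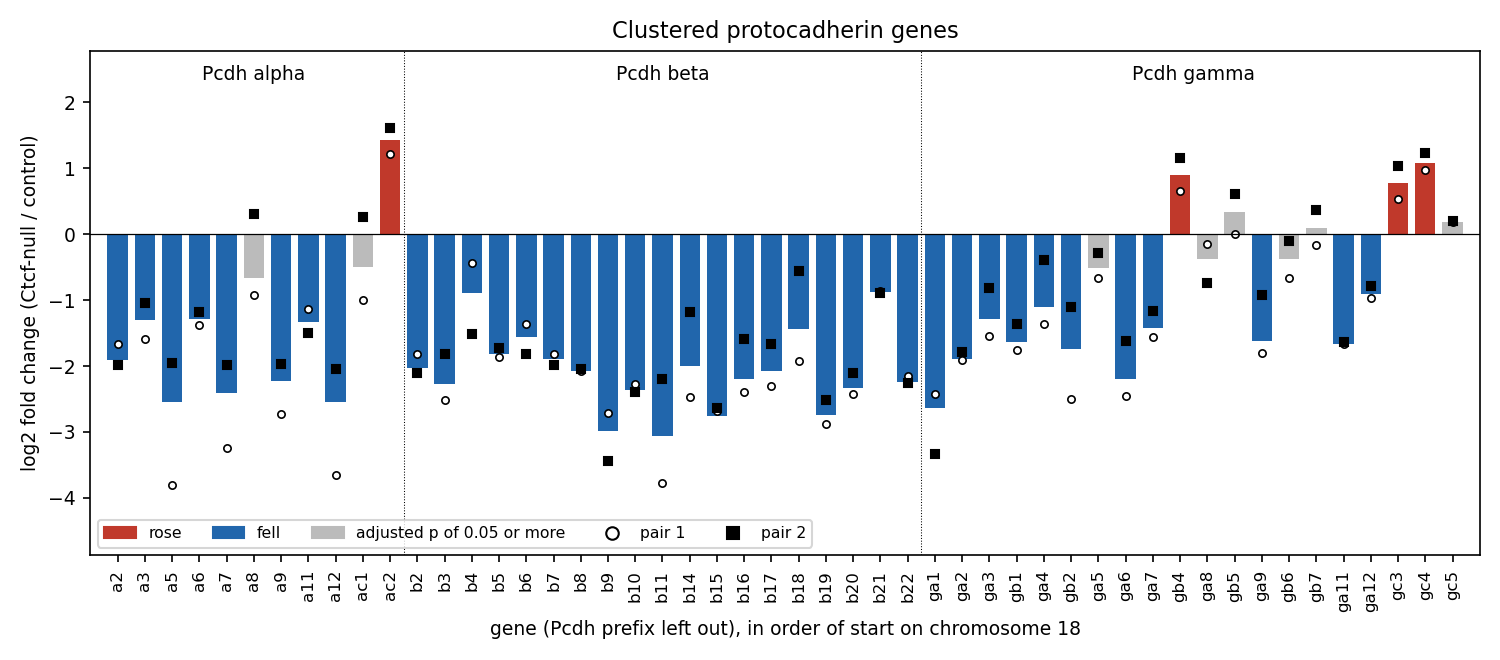
Log2 fold change (Ctcf-null over control) of each measured clustered protocadherin gene, in order of its start on chromosome 18, with the paired fit as bars, pair 1 as open circles and pair 2 as filled squares. All 19 beta genes are below 0, while Pcdhac2, Pcdhgb4, Pcdhgc3 and Pcdhgc4 rose and are above 0, as are Pcdhgb5, Pcdhgc5 and Pcdhgb7, which did not pass (0.34, 0.19 and 0.10).

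Genes of the ventral telencephalon and of the inhibitory interneurons born there were lower. In this list 11 of 25 measured genes fell and 0 rose (15 and 1 adjusted over the list alone), with a median of -0.49 and a camera adjusted p of 2.3e-16 (adjusted p = 0.60 with an estimated correlation). Besides Sst, the neuropeptide gene Npy fell from 656.41 and 1626.02 normalized counts to 164.05 and 353.53 (log2 fold change -2.05, SE 0.11). The transcription factor genes Lhx6 and Dlx2 both had -1.21, though the pairs of Dlx2 differed, at -0.35 and -1.75. Isl1 had -0.65, and the GABA-synthesizing enzyme gene Gad2 had -0.64. The pair medians of this list were -0.11 and -0.62. In the same libraries the lists for choroid plexus and for microglia had medians of 0.25 and 0.26.

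Genes of the excitatory lineage of the dorsal telencephalon were lower as well. Among intermediate progenitor genes 5 of 11 fell and 0 rose (9 and 0 adjusted over the list alone), with a median of -0.38 and a camera adjusted p of 5.7e-08 (adjusted p = 0.60 with an estimated correlation). Sstr2, a somatostatin receptor gene, fell by 1.51 (SE 0.08) and the proneural gene Neurod4 by 1.18 (SE 0.16). Neurog1 had -2.17 and Neurog2 -0.67. Eomes, a common marker of these cells, was at -0.23 and did not pass (adjusted p = 0.12). Of the excitatory cortical neuron genes 9 of 18 fell and 1 rose (10 and 1 adjusted over the list alone), with a median of -0.23 and a camera adjusted p of 7.0e-08 (adjusted p = 0.60 with an estimated correlation). Neurod1 fell from 3768.57 and 3492.19 to 1079.04 and 1208.81 normalized counts (log2 fold change -1.62, SE 0.08) and Bcl11b, a gene of deep-layer neurons, fell by 1.13 (SE 0.08). Fezf2 was at -0.68 and Slc17a6 at -0.79, and the gene that rose was Rorb, at 0.30. Tbr1 was at -0.16 and did not pass (adjusted p = 0.30). Among apical progenitor genes 5 of 21 fell and 1 rose (6 and 1 adjusted over the list alone), with a median of -0.15 and a camera adjusted p of 0.024 (adjusted p = 0.60 with an estimated correlation). Without the block this list did not pass (adjusted p = 0.073), nor with upper-quartile factors (0.053) or a stricter filter (0.19) under the block. Fabp7, a fatty acid binding protein of radial glia, fell by 0.56 (SE 0.07) and Lhx2 by 0.60 (SE 0.08), while Pax6 rose by 0.26. General neuronal genes went both ways, 3 up and 3 down of 20 (3 and 6 adjusted over the list alone, camera adjusted p = 0.47), with Tubb3 at -0.46 (SE 0.07) and Elavl4 at -0.42 (SE 0.07), and Nefm at 0.42.

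Cell cycle genes were slightly lower. Of the DNA replication genes 5 of 22 fell and 0 rose (9 and 1 adjusted over the list alone), with a median of -0.19 and a camera adjusted p of 7.8e-04 (adjusted p = 0.67 with an estimated correlation). With the stricter filter the adjusted p was 0.058. Rrm2, a subunit of ribonucleotide reductase, stood apart with a fall of 1.36 (SE 0.10), from 19223.51 and 12301.48 to 5701.4 and 5854.54 normalized counts, and Chaf1b fell by 0.45 (SE 0.09). Of the mitosis genes 9 of 22 fell and 0 rose (14 and 0 adjusted over the list alone), with a median of -0.23 and a camera adjusted p of 7.4e-05 (adjusted p = 0.60 with an estimated correlation). Ccnb1 fell by 0.33 (SE 0.07) and Ube2c by 0.32 (SE 0.07).

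Genes induced by p53 moved in part. Of 31 measured targets 5 rose and 2 fell (6 and 3 adjusted over the list alone), with a median of 0.09 and a camera adjusted p of 0.041 (adjusted p = 0.60 with an estimated correlation). Without the block the list did not pass (adjusted p = 0.16), nor under the block with the authors' size factors (0.055), DESeq2 (0.077) or the stricter filter (0.16). Ass1, an enzyme of arginine synthesis, rose by 1.33 (SE 0.13), and the others that rose were Eda2r at 1.50, Pmaip1 at 1.32, Cdkn1a at 0.71 and Ccng1 at 0.53. Btg2 fell by 0.63 (SE 0.07), as did Plk2, at -0.33. Bbc3 was at 0.54 (adjusted p = 0.061) and Mdm2 at 0.00 (adjusted p = 0.98), and neither passed. In the integrated stress response list 6 of 15 fell and 0 rose (9 and 0 adjusted over the list alone), with a median of -0.23 and a camera adjusted p of 5.3e-04 (adjusted p = 0.63 with an estimated correlation). Mthfd2, of mitochondrial folate metabolism, fell by 0.73 (SE 0.09) and the cystine transporter gene Slc7a11 by 0.47 (SE 0.07). In the hypoxia list 4 of 15 rose and 0 fell (4 and 0 adjusted over the list alone), with a camera adjusted p of 0.0043 (adjusted p = 0.60 with an estimated correlation). Without the block it did not pass (adjusted p = 0.20). Ndrg1 rose by 1.01 (SE 0.10) and Pdk1, a kinase that limits pyruvate oxidation, by 0.88 (SE 0.11). The list's median was 0.06, against -0.02 for all tested genes. After correction for GC content and exon length these medians were -0.01 and -0.12, and the list still passed (adjusted p = 0.0082).

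Imprinted genes, several of whose control regions bind CTCF, changed in both directions, 5 of 35 up and 5 down (6 and 5 adjusted over the list alone, camera adjusted p = 0.15), with a median of -0.01, a mean of 0.03 and an upward test direction. Asb4 rose from 801.39 and 609.13 to 2505.28 and 1632.81 normalized counts (log2 fold change 1.60, SE 0.09) and Peg3 rose by 0.58 (SE 0.08). Peg10, Mest and Kcnq1ot1 also rose, and Dio3, Rasgrf1, Nnat, Sgce and Grb10 fell. H19 was at -0.23 (adjusted p = 0.19) and Igf2 at -0.01 (adjusted p = 0.96), and neither passed. Of 17 genes for CTCF, cohesin and chromatin partners, Ctcf fell and Stag1, a cohesin subunit, rose by 0.70 (SE 0.09), from 866.32 and 742.97 to 1234.61 and 1286.56 normalized counts. Adjusted over the list alone, 2 rose and 1 fell. The cohesin genes Rad21 at -0.05, Smc1a at -0.05 and Smc3 at 0.01 did not pass. The list's median was 0.01, its mean -0.16 and its test downward and not passed (camera adjusted p = 0.33). After correction for GC content and exon length the adjusted p was 0.0082. Both values include Ctcf itself. Without it the mean of the other 16 genes was 0.07 (camera adjusted p = 0.26). After the correction it was -0.11 (camera adjusted p = 0.60), where the median of all genes was -0.12.

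**Figure D4:**
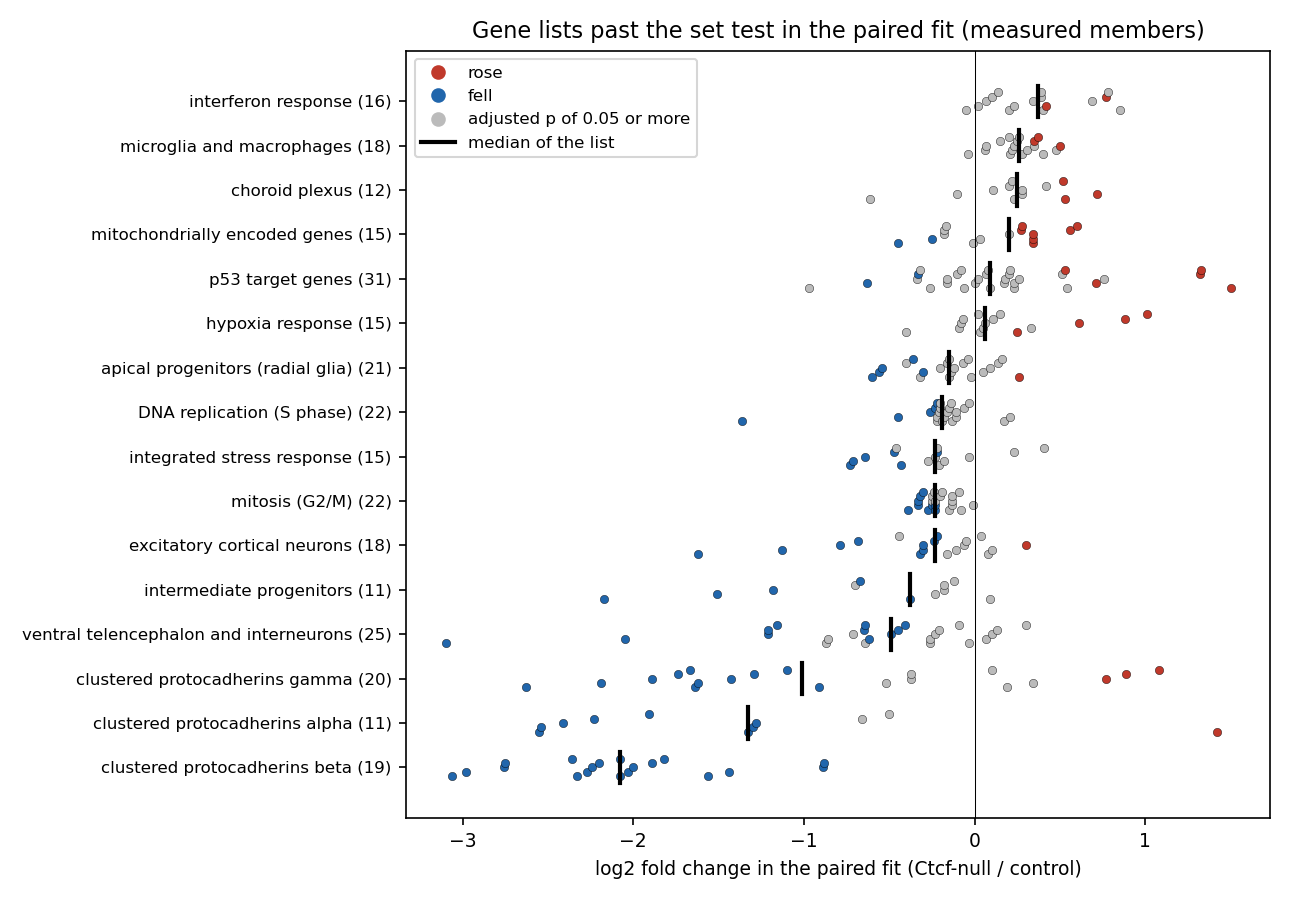
Log2 fold change in the paired fit (Ctcf-null over control) of each measured member of the 16 lists past the camera test, 1 list per line, with genes that rose in red, genes that fell in blue, other members in grey and the list's median as a black bar. Medians run from -2.08 for the beta protocadherins to 0.37 for the interferon response.

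Lists for choroid plexus, microglia, the interferon response and mitochondrially encoded genes (a mark of RNA quality) also passed the paired camera test. Lists of several other cell types did not, as given below. In the choroid plexus list 3 of 12 rose and 0 fell (4 and 0 adjusted over the list alone), with a median of 0.25 and a camera adjusted p of 0.0080 (adjusted p = 0.60 with an estimated correlation). Ttr, the transthyretin gene, rose by 0.52 (SE 0.07) and Otx2 by 0.53 (SE 0.12). In the microglia and macrophage list 3 of 18 rose and 0 fell (4 and 0 adjusted over the list alone), 16 of 18 were higher in both pairs, and the median was 0.26 with a camera adjusted p of 0.0018 (adjusted p = 0.60 with an estimated correlation). C1qb rose by 0.50 (SE 0.11) and P2ry12 by 0.37 (SE 0.12). In the interferon list 2 of 16 rose and 0 fell (4 and 0 adjusted over the list alone), namely B2m by 0.42 (SE 0.09) and Usp18 by 0.77 (SE 0.24), with a median of 0.37 and a camera adjusted p of 0.0067 (adjusted p = 0.60 with an estimated correlation). With the stricter filter the adjusted p was 0.12. Of 15 mitochondrially encoded genes 7 rose and 2 fell (8 and 5 adjusted over the list alone), with a median of 0.20 and a camera adjusted p of 0.043 (adjusted p = 0.80 with an estimated correlation). This list did not pass without the block (0.19) or under the block with limma (0.065), the authors' size factors (0.13), RLE factors (0.066) or the GC content and length correction (0.13). Among these, mt-Nd3 rose by 0.60 (SE 0.09) and mt-Nd2 by 0.56 (SE 0.09). Mitochondrially encoded genes took 2.42% and 2.65% of reads in controls and 3.34% and 2.87% in Ctcf-null libraries. Erythroid genes took 3.66% and 1.67% in controls and 2.99% and 2.02% in Ctcf-null libraries, and 0 of 11 passed (0 adjusted over the list alone, camera adjusted p = 0.28), with Hba-a1 at -0.19 (SE 0.10).

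In the remaining lists the paired camera test did not pass. Among glial precursor genes 3 of 9 rose and 2 fell (3 and 2 adjusted over the list alone, adjusted p = 0.15), with Aldh1l1, of folate metabolism, up by 1.08 (SE 0.09) and Fgfr3 at -0.56 (SE 0.09). In the Cajal-Retzius list 1 of 11 rose and 1 fell (1 and 1 adjusted over the list alone, adjusted p = 0.33), Reln at 0.31 (SE 0.08) and Nhlh2 at -0.43 (SE 0.13). In the extracellular matrix list 1 of 21 rose and 1 fell (1 and 1 adjusted over the list alone, adjusted p = 0.85), Vcan at 0.45 (SE 0.08) and Agrn at -0.29 (SE 0.08). Meningeal fibroblast genes had 2 rises and 1 fall of 15 (3 and 1 adjusted over the list alone, adjusted p = 0.18), with Bmp7 at 0.51 (SE 0.11) and Foxp1 at -0.35 (SE 0.08). Endothelial genes had 2 falls of 20 (2 adjusted over the list alone, adjusted p = 0.15), Sox17 at -1.31 (SE 0.29) and Esam at -0.30 (SE 0.09). Of the mural cell genes 1 of 12 fell (1 adjusted over the list alone, adjusted p = 0.33), namely Acta2 at -0.69 (SE 0.14). Immediate early and heat shock genes had 2 falls of 13 (4 falls and 1 rise adjusted over the list alone, adjusted p = 0.14), Dusp1 at -0.59 (SE 0.10) and Jun at -0.37 (SE 0.10). For neural tissue outside the telencephalon 2 of 5 measured genes rose (3 up and 1 down adjusted over the list alone), Pou4f1 at 0.98 (SE 0.28) and Tcf7l2 at 0.29 (SE 0.09). This list passed without the block (adjusted p = 0.023) and not with it (adjusted p = 0.14), and not with an estimated correlation in either fit (adjusted p = 0.55 and 0.63). The list for skin, muscle and cartilage likewise passed without the block (adjusted p = 0.028) and not with it (adjusted p = 0.33), and not with an estimated correlation (adjusted p = 0.55 and 0.83). In it 3 of 9 rose and 2 fell (4 and 2 adjusted over the list alone), the median was 0.68 and the test upward, and 7 of 9 were higher in both pairs. Acan rose by 1.66, Krt18 by 0.80 and Tnnt1 by 0.70, while Col2a1 was at -0.95 (SE 0.13) and Acta1 at -0.82 (SE 0.14). None of the 4 sex-linked genes measured passed (0 adjusted over the list alone, adjusted p = 0.85), with Eif2s3y at 0.00 (SE 0.08).

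Of the 73 named genes past the threshold in the paired fit, 56 were past it in each alternative of tool, scaling, filter and correction under the block that tested them. Of these, 35 were tested in all alternatives, and 21 had too few reads for the stricter filter. None of the 73 changed sign where tested. The other 17 were not past it in at least 1 of them. They were Tubb3, Reln, Nhlh2, Vcan, Agrn, Bmp7, Sox17, Esam, Acta2, C1qb, P2ry12, Otx2, Pou4f1, Tcf7l2, B2m, Usp18 and Jun. The pairs also differed for Neurog2 (-0.37 and -0.87), Rrm2 (-1.69 and -1.02), Cdkn1a (1.10 and 0.48), Usp18 (1.03 and 0.34), mt-Nd2 (0.85 and 0.27) and mt-Nd3 (0.87 and 0.34).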

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

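A replicate block in edgeR was planned as an alternative, but its use on recovered reads, the paired fit, was decided after the table was seen. Its variations, other pseudocounts, the unblocked edgeR fit and limma with the block were chosen after seeing the data. Without the block, the count of 0 genes stayed 0 under scaling factors, filters, pseudocounts, thresholds and limma-voom. It was 9 in DESeq2, and with the replicate block 2643 in edgeR and 3041 in limma. Leaving out 1 library at a time gave 0 to 4 genes, the lone library of a genotype being assumed to vary like the other genotype. Without control 1, 4 genes passed (Ctcf, Gm37933, C130021I20Rik and Rn18s-rs5), without Ctcf-null 1, 2 (Tuba1a and Ubb), and without Ctcf-null 2, 1 (RP24-286J21.7). The paired fit called 2427 to 3750 genes with other scalings, limma, voom, no filter, library sizes without erythroid and mitochondrial genes, or GC content and length trends removed, and 832 in DESeq2, 1031 with the stricter filter (at least 10 CPM in 2 libraries, which left fewer genes), 1494 at an adjusted p under 0.01 and 515 at 2-fold. No gene was called in the opposite direction in any of these, and 826 calls were shared by all 6 scaling and tool alternatives. The correction for GC content and exon length gave 748 rises and 3002 falls and moved the median of all genes from -0.02 to -0.12. Its fitted trends included the mean level of each library, which the TMM factors adjust as well. That level was thus adjusted a second time, so these shifts cannot be credited to GC content and exon length alone. The log2 fold change of Ctcf passed in DESeq2 (-3.92), with the replicate block in edgeR (-3.80) and limma (-3.81), and without control 1 (-4.50); it ranged from -4.50 to -3.13 when 1 library was left out. The 14 lists past the test without the block became 9 with no filter, 7 to 12 when 1 library was left out (7 without control 1 and 7 without Ctcf-null 1), and 0 with an estimated correlation or with fry. The 16 of the paired fit also became 0 with either, though both had little power here, as given above. The counts for fry are of its directional tests. Its test for change in either direction passed in the paired fit for 5 lists, p53 targets, alpha protocadherins and hypoxia (adjusted p = 0.024 each) and excitatory neurons and extracellular matrix (0.048 each). The causes were not tested. With the block, leaving out 1 library leaves no residual degrees of freedom, so no such test was made. No named gene past the threshold changed sign in any alternative that tested it, with 35 calls lost and 1 gained over 725 comparisons. No list past the test changed its direction, with 11 calls lost and 7 gained. The gains were architecture genes after the GC content and length correction (camera adjusted p = 0.0082, and adjusted p = 0.60 without Ctcf itself, a test chosen after seeing the data), imprinted (0.010) and glial (0.0054) genes with the stricter filter, endothelial (0.033) and erythroid (0.029) genes with no filter, neural tissue outside the telencephalon in limma (0.031), and immediate early and heat shock genes in voom (0.046).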

Other observations

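The lists, motif and gene pairs in this part were chosen after the table of all genes was seen. The direction test of neighbouring genes, the test of meiotic genes without Mnd1 and the exchange of labels were chosen after a first result was seen. Nuclear genes of 3 families, chosen after their values were seen, had medians slightly below 0. Of 76 cytosolic ribosomal protein genes 12 fell and 0 rose in the paired edgeR fit, 65 were lower in both pairs, and the median log2 fold change was -0.12 (camera adjusted p = 6.8e-05, and adjusted p = 0.32 with an estimated correlation). Of 76 mitochondrial ribosomal protein genes 6 fell and 0 rose, with a median of -0.14 (camera adjusted p = 4.8e-05, and adjusted p = 0.32 with an estimated correlation). Mrpl23 at -2.39 and Mrps2 at -1.67 stood far below the rest. Of 45 genes with Nduf names, mostly for subunits and assembly of respiratory complex I, 11 fell and 0 rose, with a median of -0.12 (camera adjusted p = 5.8e-05, and adjusted p = 0.32 with an estimated correlation), led by Ndufb7 at -1.29 and Ndufaf3 at -1.22. Among the 45 were Ndufa4 at -0.06 and Ndufa4l2 at -0.24, which are not complex I subunits and did not pass. The mitochondrially encoded genes, which include other complex I subunits, had a median of 0.20. The counts of falls depended on scaling. With the authors' size factors 27 cytosolic ribosomal, 20 mitochondrial ribosomal and 16 Nduf genes fell, with RLE factors 21, 11 and 12, with upper-quartile factors 4, 4 and 6, and after correction for GC content and exon length 9, 25 and 10. The medians of these 3 lists stayed negative under every scaling tried, and after correction for GC content and exon length they lay 0.04 to 0.08 below the median of all genes, against 0.10 to 0.12 before it.

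Among ephrins and Eph receptors, which guide axons and cell position, 4 of 22 fell (Ephb1 at -0.67, Efnb1 at -0.66, Epha5 at -0.40 and Epha4 at -0.33), and the list as a whole did not pass (camera adjusted p = 0.32). Among semaphorins and plexins Plxnc1 rose by 0.76 and Sema7a by 0.71 (list adjusted p = 0.56). The 12 protocadherins outside the clusters held 1 rise, Pcdh20 at 0.52 (list adjusted p = 0.34), and the median of 377 zinc finger protein genes was -0.02 (list adjusted p = 0.56). Of 39 genes with the Psm names of proteasome subunits 5 fell and 1 rose (median -0.10, list adjusted p = 0.050, which did not pass). They include Psmc3ip at -0.19, which is also in the list of meiotic genes and is not a proteasome subunit. Without the block the proteasome list passed (camera adjusted p = 0.035), and with an estimated correlation in the paired fit it did not (adjusted p = 0.58). With the authors' size factors 12 of its genes fell, and with upper-quartile factors 0. Non-coding genes were 8.65% of the genes that rose and 4.05% of those that fell, against 14.5% and 15.0% of the other tested genes. The groups were not matched for expression level, on which a call depends, so the shares do not show that non-coding genes respond less. Among genes that rose 4-fold or more they were 16.7%, against 14.2% of other genes (odds ratio 1.21, interval 0.488 to 2.62), and among those that fell 4-fold or more 7.84% (odds ratio 0.514, interval 0.134 to 1.41).

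Nearby genes moved in opposite or like directions at several places. Pkib rose by 3.05 while Fabp7, which starts 43768 bases beyond its end, fell by 0.56. Def8 and Tubb3, separated by 1511 bases, had -2.80 and -0.46. The antisense transcript Gm38250 rose by 2.95 and ends 58458 bases before Ctcf. Counted over all adjacent tested genes without the clustered protocadherins, 261 pairs were both called in one direction, against a mean of 163 when calls were permuted among genes of like mean expression (permutation p = 1.0e-04, the smallest that 10000 permutations can give), which argues against chance placement. Among neighbours at least 5000 bases apart with different name stems the excess was 125 against 86.7 (permutation p = 1.0e-04), but opposite directions were in excess there too (107 against 81.1, permutation p = 0.002), so the bound first written did not isolate shared direction. With the places of calls held and directions permuted, these distant neighbours shared a direction in 125 of 232 cases (mean 120, permutation p = 0.3), and the close or same-stem ones in 136 of 181 (mean 93.5, permutation p = 1.0e-04). A candidate explanation for the shared direction is therefore reads shared by overlapping genes and related families, since strand was not used as far as is known, and regulation shared over short distances stays open. These counts kept the mitochondrial genome, where the adjacent mt-Tq, mt-Tm, mt-Nd2 and mt-Ty all rose. The part of the close cases that came from it was not counted.

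The consensus CCASYAGRKGGCR of CTCF binding was searched on either strand, with 1 mismatch allowed, in the first 200 bases of the transcripts of protein-coding genes. It was found in 70 of 1292 genes that fell (5.42%) and in 567 of 13751 genes not called (4.12%), an odds ratio of 1.33 (95% interval 1.02 to 1.72, Fisher's exact p = 0.030, 0.12 after adjustment over 4 tests). Genes that rose had an odds ratio of 1.10 (0.776 to 1.51). The reversed consensus, of the same bases, gave 0.843 for genes that fell (0.461 to 1.43), an interval that includes 1.33, so base composition cannot be told apart from the motif with so few hits. Of 211 protein-coding genes that fell 2-fold or more, 4 (1.90%) carried the consensus, and of 201 that rose 2-fold or more, 6 (2.99%). The higher share among genes that fell thus did not come from the largest falls. These shares rest on few hits and were not tested, and a direct effect of a site near the start is not shown. In all of these counts a gene was a hit if any of its annotated transcripts held the consensus. The groups were not matched for number of transcripts or for expression level, on which a call depends.

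The paired fit called 2643 genes and the fit without the block 0. The difference between pairs followed GC content (r = 0.39 across 15878 genes) and exon length weakly (r = -0.08), and the paired fold change did so too (r = -0.14 with GC content and 0.16 with exon length). Genes that fell had a median exon length of 2990 bases and genes that rose 4602. After trends on both were removed per library under the block, 84.0% of the calls kept their call and direction. The correction also lowered the fold changes of genes in general (median -0.12), as given above, which favours falls. Rises went from 1063 to 748 and then made up 19.9% of the calls. The share kept therefore does not decide whether such trends are the whole cause. Exchanging the labels within the second pair called 0 genes under the same block. The exchange turns any change shared by both pairs (r = 0.41 between their fold changes) into residual spread, so whether the block alone makes calls without a genotype effect stays open. What differs between the pairs, and whether a difference in dissection or embryo stage within both pairs could add to the genotype effect, was not tested. Cre is described only for the Ctcf-null embryos, so an effect of Cre itself cannot be told apart from loss of Ctcf.

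Mnd1 led to a list of 28 meiotic genes, of which Mnd1, Zcwpw1 at 1.97, Dazl at 1.50 and Dmc1 at 1.06 rose and Rec8 fell, at -1.21 (-2.06 and 0.37 in the pairs). Without Mnd1, 3 of 27 rose (11.1%, against 4.79% of other genes, Fisher's exact p = 0.14), camera gave p = 0.0087 on values and 0.074 on ranks, and the median was 0.08. For all 28 genes the camera adjusted p was 6.8e-05 (adjusted p = 0.32 with an estimated correlation), and the median was -0.11 after the GC content and length correction, 0.01 above that of all genes, with 4 rises and 1 fall as before.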
